A study of Homo sapiens with 3 samples.

How the data were processed

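Total RNA from 3 cultures of the H9 line was measured on Affymetrix human expression arrays, with 1 array each for neuroepithelial cells at day 17, astrocytes at day 210 after retinoic acid, and astrocytes at day 210 after FGF8, both morphogens given from day 10 to day 21. Per the labels' protocols, RNA was taken with Trizol and a column cleanup, and a core facility labelled it with biotin by the manufacturer's procedure. The deposited values are an intensity for each of 54675 probe sets. The values show that the authors or their core facility scaled each array so that the mean without the lowest and highest 2% of probe sets was about 150.0 (149.979, 149.977 and 149.978), while the signal algorithm is not given in the sources used here. The intensities are linear and were brought to log2 after normalization.

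Choices of normalization, floor, size threshold, gene lists, named genes and alternatives were made before the data were examined, except where a later choice is named. The 75th percentiles of the arrays differed by 0.14 log2 units, past the tolerance of 0.1 set for using deposited values as they were, so quantile normalization across the 3 arrays was applied. The floor was the median of the 54613 non-control probe sets over the 3 arrays, a signal of 26.4 or log2 4.72, and lower values were raised to it. A difference with either side at the floor is a lower bound, written as at least so many fold, and a gene at the floor on both arrays has no difference. A value just above the floor counted as measured, so some exact folds are close to bounds. Of the non-control probe sets 41091 carried 1 gene symbol, 1801 several and 11721 none. Probe sets with several or no symbols were left out of gene counts. Gene identifiers of 41043 probe sets matched a human reference gene table (GRCh38.p14), used for names only, and 0 symbols were updated. Each of 19775 genes was represented by its probe set with the highest mean, leaving out the cross-hybridising type (_x_at) where the gene had another. Probe sets of HLA genes can still bind several family members. Genes without a probe set of 1 symbol, such as HOXA5, were not analysed here.

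The 3 comparisons were RA astrocytes minus neuroepithelial cells, FGF8 astrocytes minus neuroepithelial cells, and RA minus FGF8 astrocytes. With 1 array per group there was no test, p-value or standard error; genes were counted by size, at least 2-fold, and called higher or lower. The overlap of both astrocyte comparisons was set against independent lists and against 100 simulations without any effect that share the neuroepithelial array. The noise of those simulations came from the spread of the RA minus FGF8 difference. In each comparison and direction the text names the 6 genes with the largest difference measured on both sides and the 4 with the largest lower bound, leaving out uncharacterised symbols, XIST and Y-linked genes. From each list it names up to 4 members per direction with the largest differences, and members within 2-fold where a count needs an example. GFAP, S100B, CD44, NFIA, SOX9, PAX6, SOX1, SOX2, OTX2, EN1, HOXB4 and OLIG2 are always named. Where another probe set of a named gene, above the floor, differed in direction from the main one, both are given.

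The 36 gene lists held genes of astroglial identity, mature astrocyte transport and metabolism, secreted synaptic factors, neuroepithelium, pluripotency, developmental timing, neurons, oligodendrocytes, HOX groups 1 to 5, HOX groups 6 to 13, forebrain and midbrain, other hindbrain genes, dorsal and ventral neural tube, retinoid response, FGF feedback, Notch, BMP and TGF-beta targets, WNT, cell cycle, cell cycle inhibitors, reactive astrocytes, MHC class I, interferon response, fibrillar matrix, basement membrane, neural crest, choroid plexus and ependyma, endoderm, microglia, endothelium, stress, cholesterol, and chromatin enzymes, with ribosomal proteins and reference genes as comparison sets. A further 3 lists (MHC class II, DLX and GABA genes, pan-neuronal genes) were chosen after seeing the data. A list's median log2 difference took lower bounds at their bound, with a 95% interval from 2000 bootstrap draws over members. It was placed among 10000 random lists of the same size matched in 20 bins of mean expression, and stood apart below percentile 2.5 or above 97.5; lists with fewer than 5 compared members got no percentile.

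Alternatives were the deposited values, equal array medians, floors at the 30th and 70th percentiles or none, the mean of all probe sets of a gene, leaving out the less specific probe sets (_x_at and _s_at), sizes of 1.5-fold and 4-fold, and random lists not matched on expression. Other probe sets of a gene were checked only if they were not of the _x_at type and were bright. Bright meant at least 2 log2 units above the floor on either array compared. Among those of genes past 2-fold, 66.4% to 78.1% also passed 2-fold in the same direction and at most 1.52% in the opposite one. Silent probe sets do not enter these shares, and 699 of the 2420 genes higher in RA than in neuroepithelial cells had such a probe set. The procedure was tested on simulated data of 19775 genes with noise of 0.25 SD. For RA minus neuroepithelial cells it recovered 50 of 50 genes made 4-fold higher, 50 of 50 made 4-fold lower and the same at 8-fold. There, 0.335% of unchanged genes passed 2-fold. The simulated arrays were built from the neuroepithelial array, with changed genes well above the floor and a noise that was set, so these shares are no error rates of the real counts. In the data, other probe sets of a gene that met the same brightness rule departed from its main one. The SD was 0.92 (RA over neuroepithelial), 0.75 (FGF8 over neuroepithelial) and 0.60 (RA over FGF8). Computations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9.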

Results

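Expression was profiled on 3 Affymetrix human arrays carrying 54675 probe sets, each hybridised with RNA from cultures derived from the human embryonic stem cell line H9, an established line. The neuroepithelial array came from cells at day 17 of differentiation, an early sheet-like neural progenitor stage. The other arrays came from astrocytes at day 210, grown from progenitors that had received either retinoic acid (RA), which gives neural tissue a caudal identity, or fibroblast growth factor 8 (FGF8), a signal of rostral brain organisers, from day 10 to day 21. There was 1 array per group, so no difference below has a replicate check, and the number of arrays limits the precision. The floor, set at the median of all non-control probe sets after normalization, left 27306 probe sets above it on each array. Above it lay 11946 genes in the neuroepithelial array, 12082 in the RA array and 11845 in the FGF8 array, of 19775 genes on the array. These near-equal counts follow from that setting and do not compare how many genes each culture expressed. Across probe sets above the floor, which are not independent replicates, log2 signals correlated at 0.903 between the astrocyte arrays, 0.805 between the RA and neuroepithelial arrays and 0.876 between the FGF8 and neuroepithelial arrays.

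Controls on the arrays differed between groups. The ratio of signal at the 3' end to the 5' end of the ACTB transcript, which climbs as RNA shortens or labelling stops short of the 5' end, was 1.33 in the neuroepithelial array, 6.67 in the RA array and 6.63 in the FGF8 array. For GAPDH the ratios were 0.984, 1.79 and 1.65. Transcripts spiked into the hybridisation were 2.62-fold brighter in the RA array than in the neuroepithelial array, a mean log2 difference of 1.39 ± 0.22 (SD, n = 18 probe sets), and 2.40-fold brighter than in the FGF8 array. Between the FGF8 and neuroepithelial arrays the same probe sets differed by 0.12 ± 0.16.

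**Figure D1:**
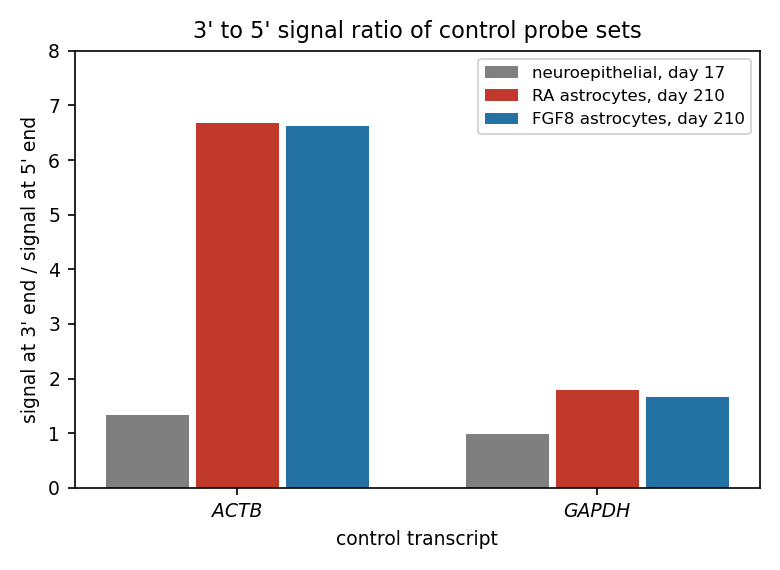
Ratio of signal at the 3' end to the 5' end of ACTB and GAPDH (unitless, axis from 0) in the neuroepithelial, RA and FGF8 arrays, with 1 bar per array and no error bars because each group has 1 array. ACTB reached 6.67 and 6.63 in the astrocyte arrays against 1.33 in the neuroepithelial array.

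The comparison of RA astrocytes with neuroepithelial cells asks what separates a caudally specified astrocyte culture from the early neural progenitor. Astrocyte genes stood among the largest differences, beside MHC class II genes: GFAP, the astrocyte intermediate filament, was at least 553-fold higher, the water channel AQP4 at least 157-fold higher and CD44, a hyaluronan receptor carried by astrocyte precursors, 227-fold higher. Genes of the embryonic progenitor programme stood at the other end, beside collagen genes and a cardiac actin. The imprinted non-canonical Notch ligand DLK1 was at least 599-fold lower and the RNA-binding protein LIN28A at least 136-fold lower. All 30 cell cycle genes were lower, and HOX genes of the hindbrain were higher. In all, 2420 of 13339 genes compared were at least 2-fold higher in the RA array, 870 of them at least 4-fold, and 1946 were at least 2-fold lower, 728 of them at least 4-fold.

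Among the largest differences measured above the floor on both arrays, CD74, the invariant chain of MHC class II, was 237-fold higher in the RA array and HLA-DPA1, an MHC class II chain, 189-fold higher. LHFPL3 was 180-fold, the adhesion molecule CHL1 177-fold and the homeodomain-only protein HOPX, found in outer radial glia and astrocytes, 154-fold higher. HLA-DRA, another class II chain, was at least 258-fold and GABBR2, a subunit of the GABA-B receptor, at least 181-fold higher. Among genes lower in the RA array, COL2A1, which encodes type II collagen, was 80.7-fold lower, HMGA2, a chromatin protein of early stem cells, 80.2-fold, the basement membrane collagen COL4A6 79.6-fold and the cardiac actin ACTC1 79.1-fold. Protogenin, PRTG, a cell surface protein of early neural tissue, was 73.0-fold and TRIM71, a partner of the LIN28 pathway, 68.3-fold lower. COL1A1, type I collagen, was at least 191-fold and the imprinted gene NNAT at least 161-fold lower.

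Of 23 astroglial identity genes compared, 14 were at least 2-fold higher, 1 was lower and 8 lay within 2-fold, with a median log2 difference of 2.49 at percentile 100 of random lists matched on expression. The transcription factor NFIX, a switch to gliogenesis, was at least 141-fold higher, NFIA 43.3-fold higher, the calcium-binding protein S100B at least 102-fold higher and the glial factor SOX9 2.96-fold higher. The glycolytic enzyme ALDOC, which marks mature astrocytes, was 4.08-fold lower, and the gap junction protein GJA1 differed by 0.37. FGFR3, an astrocyte receptor, was 1.86 higher on its main probe set, and another of its probe sets gave -0.38. Mature transport and metabolism genes were mixed (8 higher, 4 lower of 17; median 0.44): the monoamine oxidase MAOB was 45.7-fold and the sodium pump subunit ATP1B2 20.3-fold higher, while the glutamate receptor GRM3 was at least 6.24-fold lower. That list stood apart from random lists under both other scalings, at percentiles 99.4 and 99.5 against 90.8, and with the lower and higher floors, at medians of 0.67 and 1.64. Secreted factors that act on synapses had a median of 0.49, with 5 higher and 3 lower of 14, among them SPARCL1, a synapse-inducing hevin, 62.7-fold higher and CHRDL1, a BMP antagonist, 25.5-fold lower.

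Of 20 neuroepithelial genes, 14 were lower and 1 was higher, with a median of -3.60 at percentile 0. The Notch effector HES5 was 40.2-fold lower, DACH1 48.2-fold lower, PAX6 3.15-fold lower and SOX1 3.17-fold lower, whereas SOX2, which neural stem cells and astrocytes share, was 0.065 on its main probe set and -1.15 on another. NES, the progenitor intermediate filament, was 1.04 higher on its main probe set and -0.55 on another. In the developmental timing list 11 of 12 genes were lower (median -3.00), including LIN28B by at least 98.2-fold. Among pluripotency genes 7 of 11 lay at the floor on both arrays, and 3 of the other 4 were lower, such as DPPA4 at 13.4-fold lower. The 30 cell cycle genes had a median of -3.36, with the survivin gene BIRC5 24.9-fold, the mitotic activator CDC20 21.3-fold and the ubiquitin-conjugating enzyme UBE2C 20.4-fold lower. Cell cycle inhibitors split, with 2 higher and 3 lower of 12 (median -0.07, and 0.38 with array medians set equal): CDKN1A was 3.24-fold higher and CDKN1C differed by -4.09. Of 17 chromatin and DNA methylation enzymes 10 were lower (median -1.18), led by the helicase HELLS at 14.5-fold and the methyltransferase DNMT3B at 7.49-fold. Neuronal genes were lower on balance (11 lower and 4 higher of 25; median -0.70), with STMN2, a microtubule regulator of young neurons, 14.6-fold lower and the growth cone protein GAP43 13.1-fold higher. Oligodendrocyte genes had a median of 0.16 (3 higher and 2 lower of 12), with OLIG2 at 0.10, but the median was 0.94 with the lower floor, 1.13 without one and 1.56 with the higher floor, where the list stood apart.

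Patterning genes separated along the head-to-tail axis. Of 10 HOX genes of paralogue groups 1 to 5 analysed, 4 lay at the floor on both arrays, and the other 6 were all higher (median 3.57). HOXB3 was 19.1-fold, HOXA2 at least 14.0-fold and HOXB4, a gene of the caudal hindbrain, at least 11.4-fold higher. HOXA2 and HOXB4 lay at the floor in the neuroepithelial array, so they could be compared only by being higher in RA. Of the more caudal groups 6 to 13, 14 of 18 genes lay at the floor on both arrays, and HOXB7 was at least 35.4-fold higher. Other hindbrain genes had a median of 1.24 (6 higher and 0 lower of 9), among them IRX1 at 8.87-fold. In contrast 11 of 14 forebrain and midbrain genes were lower (median -2.04), with the forebrain factor EMX2 at least 55.3-fold, OTX2 47.1-fold and the eye-field and forebrain factor SIX3 at least 38.8-fold lower, while the midbrain-hindbrain gene EN1 was at least 2.71-fold higher. Dorsal neural tube genes were mostly lower (6 of 11; median -1.16), although PAX7 was 12.1-fold and PAX3 6.77-fold higher. Ventral genes had a median of -0.55 over 5 genes, with NKX2-1 at least 7.08-fold lower; with the lower floor the median turned to 0.097, and without a floor to 1.37, at percentile 97.8.

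Signalling lists had medians below 0 in the RA array, taken at day 210 after morphogen treatment up to day 21, with the FGF list turning under another scaling. In the retinoid list 8 of 15 were lower (median -1.28), with the carrier CRABP2 31.8-fold lower, but the retinol dehydrogenase RDH10 was 14.9-fold and the retinoid-inducible PLAAT4 at least 32.2-fold higher; the list reached percentile 8.82 with a floor at the 70th percentile. Of 15 BMP and TGF-beta targets 9 were lower (median -1.76), with ID1 25.9-fold lower and TGFB2 10.0-fold higher. In the WNT list 8 of 16 were lower (median -0.87), with the receptor FZD5 28.8-fold lower and the antagonist DKK3 9.04-fold higher. The Notch list had a median of -0.56 (4 lower and 2 higher of 16), with HEY1 14.9-fold lower. FGF feedback genes had a median of -0.36, which became 0.12 with array medians set equal, with 3 higher and 6 lower of 18, the cyclin CCND1 at least 40.4-fold lower among them.

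Antigen presentation and interferon genes were higher in the RA array. Of 13 MHC class I genes 11 were higher and 0 lower (median 2.76), with the peptide transporter TAP1 13.3-fold and the immunoproteasome subunit PSMB9 at least 18.0-fold higher. Of 16 interferon-stimulated genes 11 were higher (median 1.43), such as IFIT2 at least 24.9-fold and IRF9 16.7-fold. Reactive astrocyte genes had a median of 0.88 (8 higher and 1 lower of 18), with the cytokine receptor OSMR 39.2-fold higher, the complement protease C1S at least 53.7-fold higher and the chemokine CCL2 at least 42.0-fold lower. Fibrillar matrix and mesenchymal genes were lower in 13 of 20 (median -2.28), with COL3A1 at least 56.8-fold lower and the crosslinking enzyme LOX 9.56-fold higher. Basement membrane and integrin genes went both ways (9 higher and 6 lower of 19; median 0.90), with LAMA4 13.8-fold higher and LAMA1 9.89-fold lower.

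Among markers of other cells, endoderm genes were lower in 7 of 9 (median -3.74), with the keratin KRT18 at least 60.2-fold and alpha-fetoprotein AFP 20.3-fold lower. The neural crest list had a median of -0.73 (5 lower and 2 higher of 10). Choroid plexus and ependymal genes had a median of -0.28 (4 higher and 4 lower of 11), endothelial genes -0.95 (1 higher and 2 lower of 5), and 13 of 14 microglia genes lay at the floor on both arrays. Stress genes had a median of 0.36 (3 higher and 3 lower of 17), which turned to -0.05 with the mean of all probe sets, with HMOX1 at least 7.14-fold higher. Cholesterol genes had a median of -0.23 (2 higher and 3 lower of 14), which became 0.03 with array medians set equal. Among the comparison sets 0 of 20 ribosomal protein genes passed 2-fold. Their median of -0.16 turned to 0.37 with the deposited values and 0.79 with array medians set equal. The 13 reference genes had a median of -0.09, which turned to 0.01 and 0.42 under the same scalings. Of these 13, 1 was at least 2-fold higher and 4 lower, with an SD of 1.35 and absolute log2 differences up to 2.85.

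Setting array medians equal moved the median of all compared genes from 0.07 to 0.35 and the share of higher genes among those past 2-fold from 55.4% to 70.8%, and the higher ACTB ratio and brighter spike-ins of the RA array accompany every group above. The median of the basement membrane list turned to -0.21 without the less specific probe sets and lay at percentile 92.5 with the mean of all probe sets, and the Notch, WNT and neural crest lists entered the range of random lists under at least 1 alternative, at percentiles 5.51, 4.61 and 10.1. With the lower floor the secreted and oligodendrocyte lists came to stand apart at percentiles 98.3 and 97.9, and the choroid plexus and endothelial lists at 0.05 and 1.96, while the cholesterol list did so at 1.35 with the mean of all probe sets and 1.19 without the less specific ones. The secreted and oligodendrocyte lists also stood apart with the higher floor and without one, the choroid plexus list without one, and the secreted list without the less specific probe sets.

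The comparison of FGF8 astrocytes with neuroepithelial cells asks the same question for the rostral specification. The FGF8 culture shared some of the astrocyte genes of the RA culture: CD44 was 156-fold higher, AQP4 at least 154-fold higher, GFAP at least 116-fold higher and NFIA 85.8-fold higher than in neuroepithelial cells. LIN28A was at least 136-fold lower here too. The FGF8 culture held HOX genes at or near the floor and higher DLX genes of the ventral forebrain. Of its 30 cell cycle genes 18 lay within 2-fold of the neuroepithelial level, but 29 lay below that level. At least 2-fold higher were 1666 of 13004 genes, 483 of them at least 4-fold, and 1332 were at least 2-fold lower, 456 of them at least 4-fold.

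The protease inhibitor A2M was 113-fold, HOPX 73.1-fold, the DNA sensor IFI16 72.3-fold and CHL1 72.2-fold higher in the FGF8 array. The lipid-binding myelin protein PMP2 was at least 197-fold and the AMPA receptor subunit GRIA2 at least 103-fold higher. ACTC1 was 96.6-fold lower, SHISA2, an inhibitor of WNT and FGF signalling, 89.8-fold, the glutathione transferase MGST1 48.7-fold, CRABP2 47.8-fold, the matricellular factor CCN2 47.3-fold and the WNT modulator SFRP2 44.3-fold lower. COL1A1 was at least 191-fold, the kinase STK26 at least 105-fold and LIN28B at least 98.2-fold lower.

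Astroglial identity genes had a median of 1.97 at percentile 100, with 12 higher, 4 lower and 7 within 2-fold of 23. S100B was at least 63.9-fold and SOX9 3.92-fold higher, while the BMP target ID3 was 10.5-fold lower. APOE, the lipid carrier, was -1.37 on its main probe set and 0.30 on another. Mature transport and metabolism genes had a median of 0.34 (7 higher and 3 lower of 17) within the range of random lists, but stood apart at 0.72 with the lower floor, at 0.83 without a floor and also without the less specific probe sets, with the glutamate transporter SLC1A3 24.2-fold and the potassium channel KCNJ10 at least 18.3-fold higher. Secreted synaptic factors split evenly, 4 higher and 4 lower of 14, with the proteoglycan NCAN 23.4-fold higher and the thrombospondin THBS1 3.87-fold lower; their median of -0.42 turned to 0.14 with array medians set equal.

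Neuroepithelial genes were lower in 12 of 20 and higher in 0 (median -1.49), with SOX3 33.7-fold and PAX6 3.64-fold lower, SOX1 at -0.29, and SOX2 at 0.41 on its main probe set and at -2.35 and -0.49 on others. Developmental timing genes were lower in 11 of 12 (median -2.91), with TRIM71 at least 81.6-fold and HMGA2 35.9-fold lower. Pluripotency genes were lower in 3 of 5 (median -2.33), and with the lower floor that median was -0.10, at percentile 39.1. Of the 30 cell cycle genes 11 were at least 2-fold lower and 1 was higher, and 29 lay below 0. Their median was -0.80 at percentile 0, and -0.23 with array medians set equal. The mitotic kinase AURKB was 5.95-fold lower and the G1 cyclin CCNE2 2.33-fold higher. Cell cycle inhibitors had a median of -0.38, which became 0.17 with array medians set equal, with CDKN1C 34.8-fold lower. Chromatin and DNA methylation enzymes were lower in 4 of 17 (median -0.56, and -0.0093 with array medians set equal), DNMT3B by 5.02-fold. Neuronal genes were mixed (7 higher and 8 lower of 23), with the GABA-synthesising enzyme GAD1 70.3-fold higher and STMN2 at least 84.9-fold lower; the median of -0.43 turned to 0.032 with array medians set equal. Oligodendrocyte genes had a median of 0.42 (4 higher and 2 lower of 10), which was 0.021 at percentile 63.8 with the mean of all probe sets, with PDGFRA, a receptor of oligodendrocyte progenitors, 34.8-fold higher and OLIG2 at 0.82.

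Of the forebrain and midbrain genes 8 of 13 were lower (median -1.12), with EMX2 at least 55.3-fold and OTX2 12.3-fold lower, yet DLX1 was 10.0-fold and DLX5 4.99-fold higher. DLX2 was 3.19 higher on its main probe set and -0.02 on another. HOX genes of paralogue groups 1 to 5 had a median of -0.15 over 4 genes, HOXB4 lay at the floor on both arrays, and so did all 18 genes of groups 6 to 13. EN1 was at the floor as well. Other hindbrain genes had a median of -0.32 (0 higher and 3 lower of 8), which was -0.0054 with array medians set equal and 0.17 without a floor, with NR2F1, a nuclear receptor, at least 42.9-fold lower; that list reached percentiles of 1.87 and 0.50 with the higher floor and without the less specific probe sets, against 8.54. Dorsal genes were lower in 6 of 11 (median -1.03), with BMP4 at least 9.95-fold lower, and ventral genes had a median of -0.55 over 5 genes, which turned to 0.29 with the lower floor.

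Retinoid genes were lower in 7 of 12 (median -1.33), with ALDH1A1, a retinoic acid synthesising enzyme, at least 15.4-fold lower and PLAAT4 at least 32.8-fold higher. BMP and TGF-beta targets were lower in 10 of 15 (median -1.95), ID1 by at least 60.1-fold, and WNT genes in 10 of 16 (median -1.56), LGR5 by at least 19.0-fold. The Notch list had a median of -0.49 (5 lower and 3 higher of 16), with HES5 13.1-fold lower. FGF feedback genes had a median of -0.02, which turned to 0.03 and 0.49 under the other scalings, with the immediate early gene EGR1 4.53-fold and the FGF-induced factor ETV1 4.32-fold higher and CCND1 at least 40.4-fold lower.

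MHC class I genes were higher in 10 of 13 (median 1.97), TAP1 by 11.8-fold, and interferon-stimulated genes in 8 of 18 with 1 lower (median 0.60), IFIT3 by at least 11.0-fold. Reactive astrocyte genes were higher in 7 of 16 and lower in 0 (median 0.94), OSMR by 44.3-fold; the cytokine feedback gene SOCS3 was 3.55 higher on its main probe set and -0.25 on another. Fibrillar matrix and mesenchymal genes were lower in 16 of 20 (median -2.24), with LUM at least 33.6-fold and the smooth muscle protein TAGLN 27.9-fold lower. Basement membrane genes had a median of 0.25 (5 higher and 5 lower of 19), which turned to -0.10 with the mean of all probe sets. Endoderm genes were lower in 8 of 9 (median -3.74), and the neural crest list in 6 of 10 (median -1.32). Choroid plexus and ependymal genes had a median of -0.28, with TTR at least 12.7-fold lower, and endothelial genes -0.35. Stress and cholesterol genes had medians of -0.24 and -0.25, which turned to 0.29 and 0.24 with array medians set equal. Of 14 microglia genes 13 lay at the floor on both arrays. Ribosomal protein genes had a median of 0.02 with 0 of 20 past 2-fold. The reference genes had a median of -0.23, which turned to 0.39 with array medians set equal. Of 13 reference genes, 1 was at least 2-fold higher and 2 lower, with absolute log2 differences up to 2.32.

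Setting array medians equal moved the median of all compared genes from 0.05 to 0.42, the higher count from 1666 to 2853 and the share of higher genes among those past 2-fold from 55.6% to 75.8%, and the ACTB ratio was as high here as in the RA array. The secreted, oligodendrocyte, neuronal, pluripotency, interferon, neural crest and retinoid lists entered the range of random lists under at least 1 alternative, the interferon list at percentiles 95.5 without a floor and 92.4 without the less specific probe sets, the neuronal list at 9.41 with the deposited values and the pluripotency list at 9.76 without a floor. The choroid plexus list came to stand apart at percentile 2.15 with the lower floor and the cholesterol list at 0.26 with the mean of all probe sets.

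**Figure D2:**
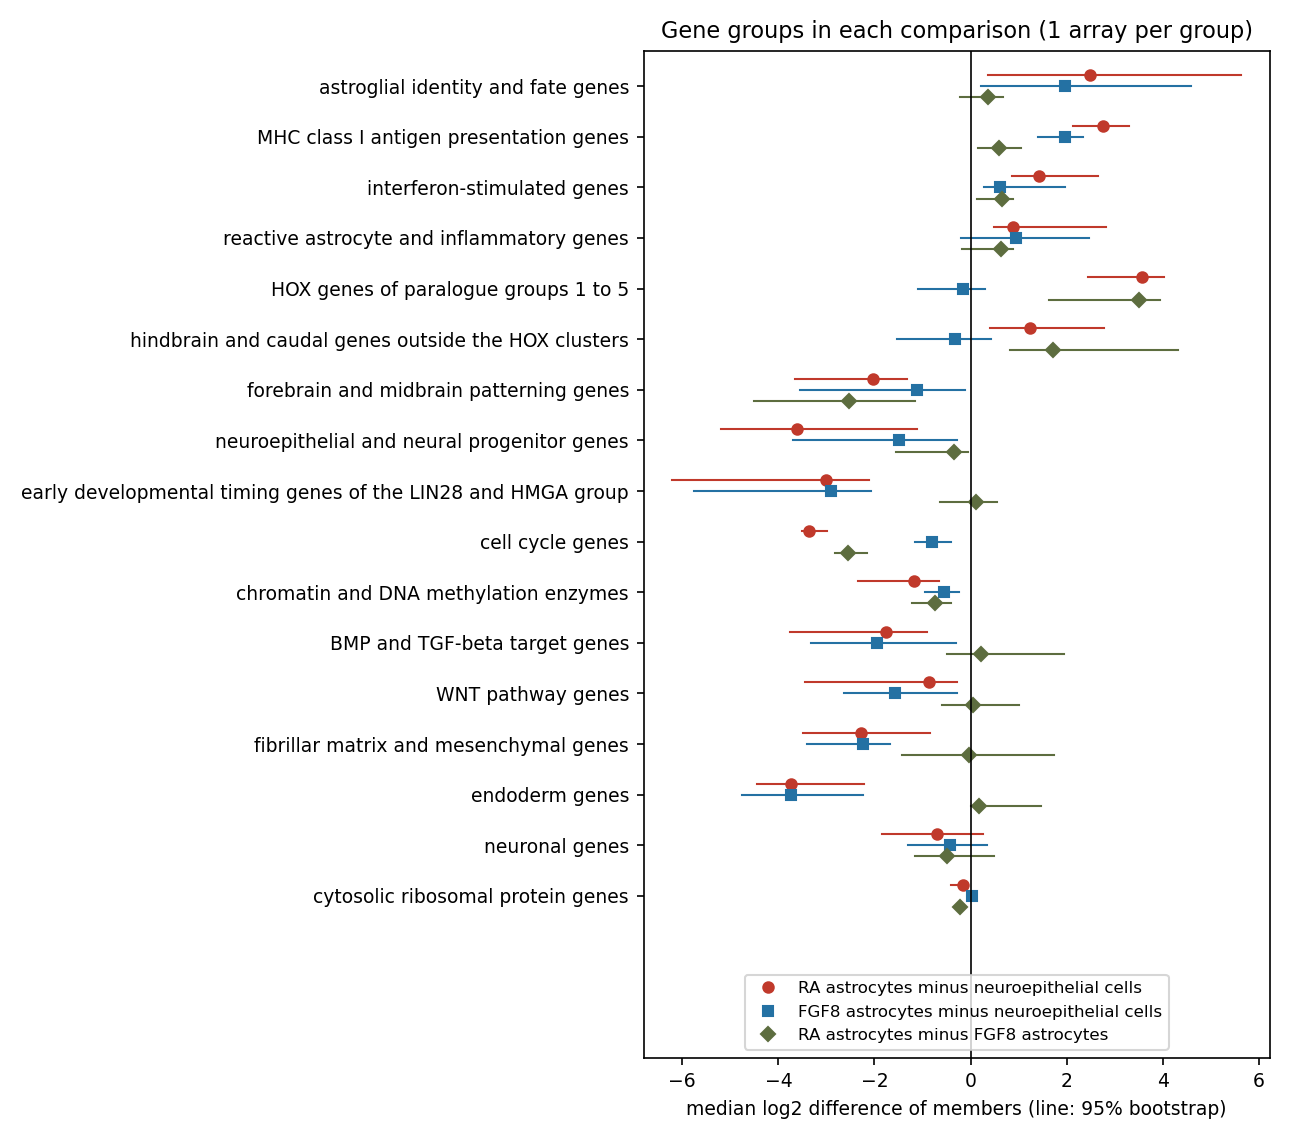
Median log2 difference of the members of 17 gene groups, with 95% bootstrap intervals over members, for RA minus neuroepithelial (red circles), FGF8 minus neuroepithelial (blue squares) and RA minus FGF8 (green diamonds), with 1 array per group. HOX genes of groups 1 to 5 lie at 3.57 in RA and -0.15 in FGF8, cell cycle genes at -3.36 and -0.80 (-0.23 with array medians set equal), and astroglial genes at 2.49 and 1.97.

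Set side by side, the astrocyte arrays shared many differences from the neuroepithelial array. Of 12605 genes compared in both, 1198 were at least 2-fold higher in both and 1002 at least 2-fold lower in both, where independent lists would share 297 and 206. Both comparisons subtract the same neuroepithelial array, and in 100 simulations with this sharing and no effect 622 and 661 genes coincided on average. The simulated noise was taken from the spread of RA minus FGF8, which can also hold differences between those cultures. The simulated counts therefore do not measure the sharing alone. The differences from the neuroepithelial array correlated at 0.756 across genes, which are not independent replicates, against 0.502 in the simulations. The simulated value follows from giving each array independent noise of the same size. A technical difference that both astrocyte arrays share was not simulated and could also raise the overlap and the correlation. Their ACTB ratios of 6.67 and 6.63 against 1.33 show such a difference. Shared higher genes included GFAP, S100B, CD44, AQP4, NFIA, SOX9, HOPX and CHL1, and shared lower genes LIN28A, LIN28B, HMGA2, TRIM71, COL1A1, ACTC1, OTX2 and PAX6. At the 4-fold size 349 genes were higher and 329 lower in both, and the higher count went from 1198 to 1978 with array medians set equal and to 758 with the mean of all probe sets.

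**Figure D3:**
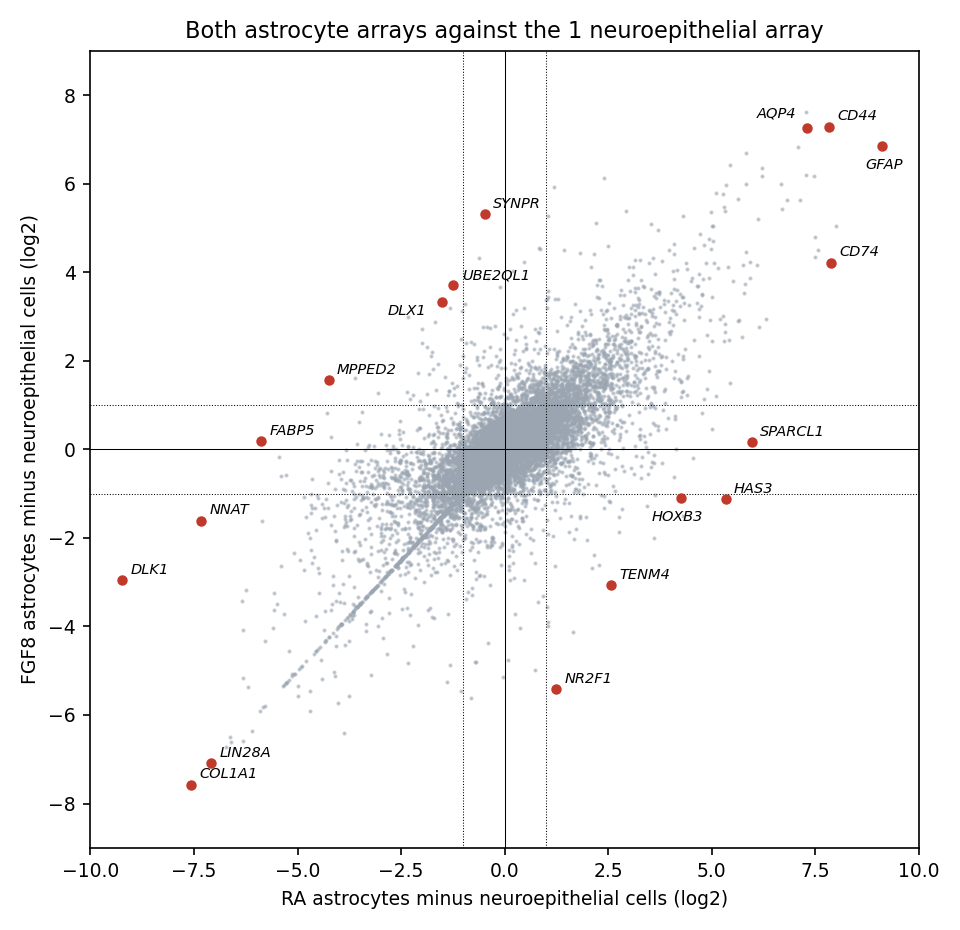
Log2 difference of each gene from the neuroepithelial array in the RA array (x axis) and the FGF8 array (y axis), with 1 array per group, dotted lines at 2-fold and 18 labelled genes. Points spread along the diagonal, whose thin lower streak holds genes at the floor in both astrocyte arrays, while NR2F1 and HAS3 sit to the lower right and DLX1 and MPPED2 to the upper left.

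The comparison of RA with FGF8 astrocytes asks how astrocytes at day 210 differ by the morphogen received early. The arrays differed in regional genes and in cell cycle genes. HOX genes and the nuclear receptor NR2F1, at least 102-fold higher, stood higher in RA astrocytes, and the ventral forebrain factors DLX1, 28.6-fold lower in RA, and SP8, 38.6-fold lower in RA, stood higher in FGF8 astrocytes. All 30 cell cycle genes were at least 2-fold lower in RA astrocytes. At least 2-fold higher in RA were 1255 of 12958 genes, 324 of them at least 4-fold, and 1018 were at least 2-fold lower, 343 of them at least 4-fold.

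HAS3, a hyaluronan synthase, was 88.0-fold higher in RA than in FGF8 astrocytes, the metalloprotease ADAMTS15 56.4-fold, SPARCL1 55.9-fold, the teneurin TENM4 49.5-fold, the trophoblast glycoprotein TPBG 34.3-fold and the protocadherin PCDH17 32.7-fold. The zinc finger gene ZNF503 was at least 54.9-fold, the neural long noncoding RNA RMST at least 52.4-fold and sarcolipin, SLN, at least 49.1-fold higher. In the other direction KCTD12, an auxiliary subunit of GABA-B receptors, was 37.6-fold lower in RA, UBE2QL1 30.7-fold, the GABA-A receptor subunit GABRQ 26.5-fold and AMER2, a WNT regulator, 26.2-fold. DLK1 was at least 76.9-fold, the fatty acid carrier FABP5 at least 67.0-fold, MPPED2 at least 56.3-fold and the synaptic vesicle protein SYNPR at least 55.3-fold lower in RA.

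Of 10 HOX genes of paralogue groups 1 to 5 analysed, 3 lay at the floor on both arrays, and 6 of the other 7 were higher in RA (median 3.51, percentile 100). HOXB3 was at least 40.8-fold, HOXB2 at least 15.3-fold and HOXB4 at least 11.4-fold higher. These named genes lay at the floor in the FGF8 array, so they could be compared only by being higher in RA. In groups 6 to 13 HOXB7 was at least 35.4-fold and HOXB6 at least 4.88-fold higher, and 14 of 18 lay at the floor on both arrays. Other hindbrain genes were higher in 5 of 9 and lower in 0 (median 1.71), with IRX3 at least 19.8-fold higher. Of 7 forebrain and midbrain genes 6 were lower in RA (median -2.53), with DLX2 22.8-fold, DLX5 18.2-fold and OTX2 3.83-fold lower, while EN1 was at least 2.71-fold higher; without a floor the median of this list was -0.15, at percentile 24.9. Dorsal genes had a median of -0.08, which turned to 0.01 with the deposited values, and held PAX3 at least 24.8-fold higher and ZIC2 26.0-fold lower. Of 4 ventral genes SHH was at least 2.23-fold higher and PTCH1, a hedgehog receptor, 2.16-fold lower.

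**Figure D4:**
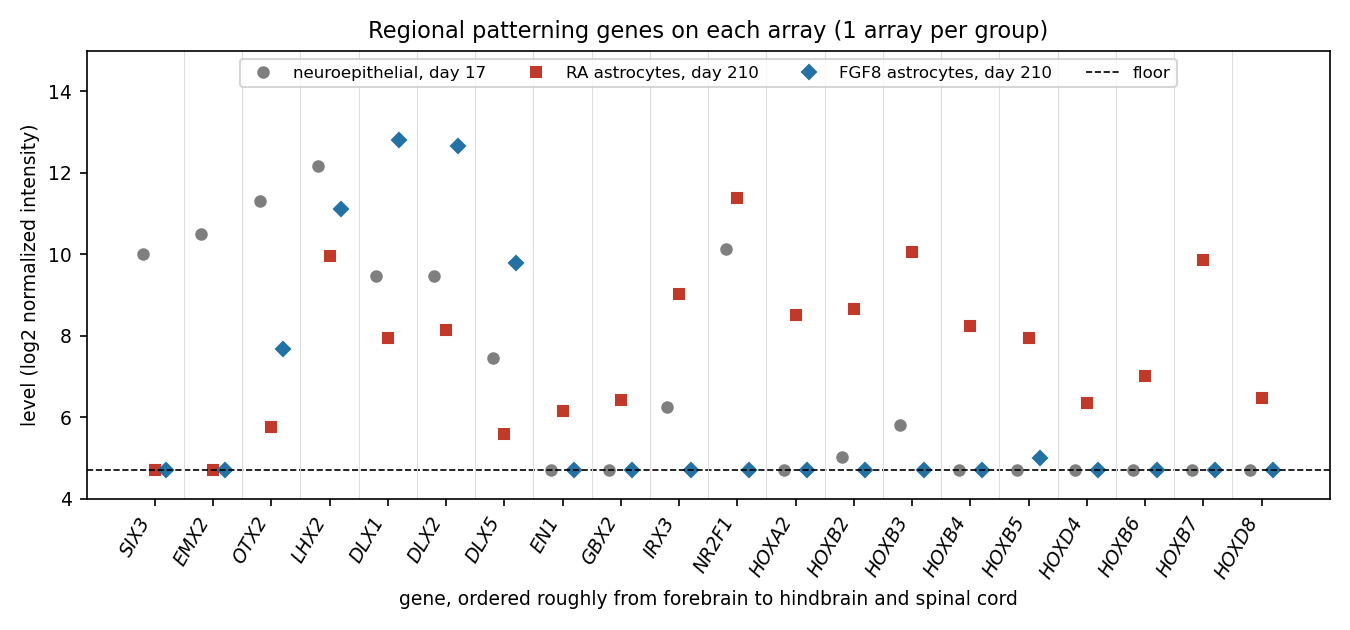
Log2 signal of 20 patterning genes in the neuroepithelial, RA and FGF8 arrays, with 1 point per array, no error bars and a line at the floor of 4.72. The HOX genes lie highest in the RA array, while DLX1, DLX2 and DLX5 are highest in the FGF8 array.

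The cell cycle list had a median of -2.55 at percentile 0, with the spindle checkpoint kinase BUB1B 13.1-fold, the ribonucleotide reductase RRM2 11.2-fold and BIRC5 10.0-fold lower in RA. Chromatin and DNA methylation enzymes were lower in 6 of 17 (median -0.74), with HELLS 4.90-fold and the polycomb methyltransferase EZH2 3.39-fold lower. Cell cycle inhibitors had a median of 0.15, with 2 higher and 2 lower of 12. Astroglial identity genes were alike in 15 of 23, with 7 higher and 1 lower in RA (median 0.36): AGT, the astrocyte angiotensinogen, was 10.5-fold and GFAP 4.77-fold higher, SLC1A3 was 4.32-fold lower, and S100B, CD44, NFIA and SOX9 differed by 0.68, 0.54, -0.99 and -0.40, with another CD44 probe set at -0.61. Another GFAP probe set lay closer, at log2 10.5 in RA and 9.38 in FGF8, against 13.8 and 11.6 on the main one. Mature transport and metabolism genes had a median of 0.09 (4 higher and 1 lower of 16), with MAOB 3.27-fold higher. Secreted factors that act on synapses split, 4 higher and 4 lower of 13 (median 0.38), with THBS1 4.37-fold higher and NCAN 13.2-fold lower.

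Neuroepithelial genes were lower in 7 of 16 and higher in 0 (median -0.35), with SOX1 2.58-fold and HES5 3.06-fold lower in RA, PAX6 at 0.21 on its main probe set and -0.11 on another, and SOX2 at -0.34 on its main probe set and 0.55 and 1.20 on others. Neuronal genes were lower in 6 of 20 and higher in 3 (median -0.49), with doublecortin, DCX, 11.6-fold and GAD1 13.2-fold lower in RA and the synaptic calcium sensor SYT1 5.09-fold higher. PDGFRA was 7.56-fold lower in an oligodendrocyte list with a median of 0.01, and OLIG2 differed by -0.72. Developmental timing genes had a median of 0.12 (1 higher and 2 lower of 9), and 8 of 11 pluripotency genes lay at the floor on both arrays, with 0 of the other 3 past 2-fold. The retinoid list had a median of 0.08 (2 higher and 1 lower of 10), with RDH10 10.9-fold and the retinaldehyde reductase DHRS3 3.20-fold higher. FGF feedback genes had a median of -0.20 (3 higher and 5 lower of 17): MYC was 7.25-fold and ETV1 4.96-fold lower, EGR1 was -1.15 on its main probe set and 0.52 on another, and FGFR2 was 1.87 and -0.18. Notch genes had a median of -0.12 (1 higher and 4 lower of 15), with HEY1 8.06-fold lower. BMP and TGF-beta targets had a median of 0.22 (5 higher and 2 lower of 12), with TGFB1 5.87-fold higher, and the WNT list one of 0.05, which turned to -0.03 with array medians set equal, with WNT5A at least 6.74-fold higher.

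MHC class I genes were higher in 4 of 14 and lower in 0 (median 0.59), HLA-E by 2.51-fold, and interferon-stimulated genes in 4 of 18 with 1 lower (median 0.65), IFIT1 by 4.56-fold. Reactive astrocyte genes were higher in 4 of 18 and lower in 2 (median 0.64), with the pentraxin PTX3 3.72-fold higher and CCL2 at least 27.5-fold lower. Fibrillar matrix and mesenchymal genes split (5 higher and 4 lower of 13; median -0.02, and 0.94 with the higher floor, where the list stood apart), with the smooth muscle actin ACTA2 18.9-fold and TAGLN 17.3-fold higher and fibronectin, FN1, 5.30-fold lower. Basement membrane genes had a median of 0.27 (6 higher and 3 lower of 18), with agrin, AGRN, 5.13-fold higher and the integrin ITGA6 10.2-fold lower. Cholesterol and lipid genes had a median of 0.06 with LPL 4.99-fold higher, which turned to -0.03 without a floor and with the higher one, and to -0.26 without the less specific probe sets. Stress genes had a median of 0.27 with 1 of 17 past 2-fold. Medians were 0.41 over 7 neural crest genes, 0.62 over 7 choroid plexus and ependymal genes, 0.17 over 4 endoderm genes and -0.39 over 4 endothelial genes. The neural crest median turned to -0.28 with the lower floor and -0.39 without one, and the endothelial median to 0.25 with the higher floor. Of 14 microglia genes 12 lay at the floor on both arrays. The 20 ribosomal protein genes had a median of -0.22, which turned to 0.28 with the deposited values and 0.23 with array medians set equal. The reference genes had a median of -0.26, with 0 higher and 1 lower of 13.

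The spike-ins were 2.40-fold brighter in the RA array beside all of these differences, while the ACTB ratios of both arrays were close. Without the less specific probe sets the astroglial and MHC class I lists entered the range of random lists, at percentiles 78.5 and 82.5, as did the neuronal list at 9.63 and the neuroepithelial list at 3.83. The neuroepithelial list did so under both other scalings, at 4.93 and 7.05, and with the lower and higher floors, at 2.80 and 4.01, and the neuronal list with the mean of all probe sets, at 16.2. With the mean of all probe sets MHC class I genes did so again, at 96.9. The Notch list came to stand apart at percentiles of 0.38 with the lower floor, 0.32 without one and 0.09 without the less specific probe sets. The BMP and TGF-beta list did so with medians of 0.88 and 0.93 under the lower and higher floors, but its median turned to -0.07 without the less specific probe sets. The secreted list came to stand apart at 98.8 with the lower floor and 99.1 without one. So did the basement membrane list at 98.5 with the lower floor and 98.1 with the mean of all probe sets, and the choroid plexus list at 98.4 with that mean.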

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

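Of the tests in this part, the test of signal loss at the 5' end was chosen before its result was seen, and none was chosen after. None of the differences between the astrocyte arrays in this part was itself tested, since each group has 1 array.

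Some genes stood on opposite sides of the neuroepithelial level. Of 12605 genes compared in both, 45 were at least 2-fold higher in RA astrocytes and at least 2-fold lower in FGF8 astrocytes, and 40 showed the reverse. The HOX list of groups 1 to 5 had medians of 3.57 in RA (6 genes) and -0.15 in FGF8 (4 genes, 2 above and 2 below 0), so it shows no clear opposite direction. The other hindbrain genes had medians of 1.24 and -0.32, and the secreted synaptic factors 0.49 and -0.42. With array medians set equal the FGF8 medians of the last 2 were -0.0054 and 0.14, so that the secreted list keeps no opposite direction there, and without a floor the hindbrain median was 0.17. Higher in RA and lower in FGF8 than in neuroepithelial cells were the hyaluronan synthase HAS3 (5.34 and -1.12), the metalloprotease ADAMTS15 (4.32 and -1.50), sarcolipin SLN (3.61 and -2.01 or lower) and the teneurin TENM4 (2.56 and -3.07). So were the zinc finger gene ZNF503 (1.65 and -4.13 or lower), the nuclear receptor NR2F1 (1.24 and -5.42 or lower) and the protocadherin PCDH17 (1.04 and -4.00). The opposite held for the forebrain factor DLX1 (-1.52 and 3.32), UBE2QL1 (-1.24 and 3.70), the WNT regulator AMER2 (-2.00 and 2.71), the GABA-B receptor subunit KCTD12 (-3.62 and 1.61) and MPPED2 (-4.25 or lower and 1.57).

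Values outside the main comparisons also differed. The spiked-in controls were 2.62-fold brighter in the RA array than in the neuroepithelial array. The ratio of 3' to 5' signal was 6.67 in the RA array and 6.63 in the FGF8 array for ACTB, and 1.79 and 1.65 for GAPDH. Among 13522 probe sets with several or no gene symbols, 183 were at least 4-fold higher in RA astrocytes and 91 in FGF8 astrocytes than in neuroepithelial cells, and 54 in RA than in FGF8 astrocytes.

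Genes lower in both astrocyte arrays, such as LIN28A, HMGA2 and COL1A1, could owe their lower signal to RNA shortened at the 5' end, given the ACTB ratios. In 227 genes lower in both with several bright probe sets, even the least lowered probe set had a median of -1.76 (95% -1.91 to -1.63). In 81.9% every such probe set was at least 2-fold lower. The genes were chosen on these same arrays for a lower main probe set, and the probe sets for brightness in the neuroepithelial array. That choice favours lower values, so these values argue only in part against a loss confined to some probe sets of a gene. The position of probe sets in the transcript was not used, so a loss that reaches all of them cannot be told from lower expression. A shift of whole arrays left by the scaling stays open in part and was not tested; 1112 genes were lower in both with the deposited values and 670 with array medians set equal, against 1002. The difference in stage between day 17 and day 210, which the design gives, remains open and was not tested. COL1A1 belongs to the fibrillar matrix and mesenchymal list, markers of other cells in the culture, with medians of -2.28 in RA and -2.24 in FGF8. The make-up of the cultures was not measured here.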

How the results depend on the processing

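The tests of genes named for their size and the medians of the lists added later were chosen after the result was seen. Counts follow the order RA over neuroepithelial, FGF8 over neuroepithelial, RA over FGF8 and both astrocyte arrays together. With a 1.5-fold size 3898, 3048, 2525 and 2199 genes were higher and 3238, 2552, 2150 and 1919 lower, and with a 4-fold size 870, 483, 324 and 349 were higher and 728, 456, 343 and 329 lower. Without a floor 4961, 3948, 3633 and 2678 were higher and 4189, 3509, 3181 and 2060 lower. These shifts follow from the size and floor themselves. With the floor at the 70th percentile 1046, 784 and 740 were higher in the last 3 and 1291, 787, 603 and 609 lower in all 4; at the 30th, 2123 were lower in FGF8 than in neuroepithelial cells, and 2222 were higher and 1721 lower in RA than in FGF8. Equal array medians gave 2853 genes higher in FGF8 and 1978 in both, and the mean of all probe sets 1083 and 758. The other counts, all of those from deposited values and without less specific probe sets included, lay within 1.5 times. List medians kept to within their spread in 757 settings, moved in 48 and, among lists that stood apart, reversed in 3: the secreted list in FGF8 to 0.14 and the neuronal list in FGF8 to 0.032 with equal array medians, and the basement membrane list in RA to -0.21 without less specific probe sets. For these and for the counts under other scalings and probe set rules the cause was not tested. Lists that did not stand apart changed sign in 47 settings, the largest the ventral list in RA, from -0.55 to 1.37 without a floor, where it stood apart at percentile 97.8. Of the list results that stood apart, 3 ceased to with equal array medians, 4 with deposited values, 3 with the lower floor, 6 with the higher floor, 5 without a floor, 7 with the mean of all probe sets, 9 without less specific probe sets and 1 with unmatched random lists. In the same order 1, 1, 11, 6, 7, 4, 5 and 0 others came to stand apart. Genes named by size moved in 112 of their settings and reversed in 0, and genes always named moved in 37. No paired analysis was possible because each group has 1 array. Signal near the floor limits what the arrays show: a gene below log2 4.72 on either side has a bound only.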

Other observations

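The tests of myeloid, interferon, DLX and GABA, pan-neuronal and cell cycle genes in this part were all chosen after the result was seen, as were the lists of MHC class II, DLX and GABA, and pan-neuronal genes.

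Antigen presentation by MHC class II, a pathway of professional immune cells that astrocytes can induce, was represented in both astrocyte arrays. Of 11 class II genes compared 11 were at least 2-fold higher in RA astrocytes than in neuroepithelial cells (median 4.05), 7 were higher in FGF8 astrocytes (median 1.99), and 11 were higher in RA than in FGF8 astrocytes (median 2.97). CD74 was 12.8-fold, HLA-DQA1 9.70-fold and HLA-DRB1 9.26-fold higher in RA than in FGF8 astrocytes. CIITA, the master regulator of the class II genes, was at least 8.71-fold higher in RA astrocytes and at least 2.46-fold higher in FGF8 astrocytes than in neuroepithelial cells. It is named here because of its known role, after its values were seen.

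DLX transcription factors and GABA genes of ventral forebrain lineages ran the other way. Of 14 compared, 9 were higher and 4 lower in FGF8 astrocytes than in neuroepithelial cells (median 2.54), against 3 higher and 8 lower in RA astrocytes (median -1.41). The vesicular GABA transporter SLC32A1 was 38.7-fold higher and SYNPR 39.8-fold higher in FGF8 astrocytes, whereas the interneuron peptide SST was at least 32.5-fold lower. Of 17 pan-neuronal genes 3 were higher and 8 lower in RA astrocytes than in neuroepithelial cells (median -0.83). In FGF8 astrocytes 5 were higher and 5 lower of 16 (median -0.21, and 0.23 with array medians set equal), with the microtubule protein MAPT 6.30-fold and DCX 3.27-fold higher and STMN2 at least 84.9-fold lower.

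The higher MHC class II genes in RA than in FGF8 astrocytes may have several sources. Myeloid cells in the culture would bring their own genes, yet 1 of 14 microglia and myeloid genes lay above the floor in the RA array, the highest at log2 4.96, which argues against them. The median of that list, RA minus FGF8, turned from -0.01 to 0.49 with the lower floor and 0.60 without one. Most of those signals lie below the main floor. Interferon signalling in the RA culture remains a candidate explanation, since interferon-stimulated genes also stood higher there, at percentile 99.9 (median 0.65, n = 18), with IFI44L as an exception, at least 6.23-fold lower. Binding of HLA probe sets to related genes stays open for the HLA members only, since CD74 (12.8-fold) and CIITA (3.54-fold) are not HLA genes, and the morphogen itself stays open; neither was tested.

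The higher DLX and GABA genes in FGF8 than in RA astrocytes may likewise have several sources. A dimmer target on the RA array was read from spike-ins, up to 1.63 brighter there in the deposited values. The list median of -4.18 (95% -4.84 to -2.40, n = 11), taken after normalization, lay beyond that size. The list was chosen after the data were seen, and the values are on different scales, so this comparison cannot decide for or against a dimmer target. Neurons in the FGF8 culture stay open, because 4 of 16 pan-neuronal genes were lower in RA than in FGF8 astrocytes, among them DCX, and 3 were higher, among them STMN2. Dividing progenitors of ventral forebrain type are a candidate explanation, with the cell cycle list at percentile 0 (median -2.55, n = 30). No separate measurement of cell types was made, and the morphogen named by the design stays open as well.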
